A study of Homo sapiens with 9 samples.

How the data were processed

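Total RNA of 9 Jok-1 samples was labelled with Cy3 and hybridised to 1 array each, per the labels' protocols. The series describes the replicates as biological, and p-values measure the spread between these arrays. The authors deposited scanner files with the intensity of every spot, made with Agilent Feature Extraction version 10.5.1.1 per the file headers, whereas the submitters' processing notes name version 9.1. The processed intensity was background-corrected by that software, per the file headers. The authors also deposited a value table of unstated scale, whose other values are relative to a level per probe. In it 28.8% of the values seemed to have lost their decimal point, which was restored before use as an alternative. Whether that repair is right is not known. Each of its columns followed its own array (r 0.977 to 0.988) more closely than any other (highest 0.257 to 0.581). Its column medians ranged from 0.813 to 0.950, and its scaling stays unknown.

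From the deposited intensity, log2 of the processed signal minus the 75th percentile of each array was taken over 43376 non-control spots. Spots flagged as outliers were set to missing and spots of 1 probe were averaged. Of 41000 probes, 24184 were well above background on all 3 arrays of at least 1 group and were tested. A gene was represented by its brightest probe, which gave 17763 genes, 4750 of them with over 1 probe. Names came from the RefSeq table of GRCh38.p14, which matched 23680 probes by accession, 2802 by symbol and 1128 by synonym, and 13390 kept the name in the file. Probe coordinates are those of the files, in hg18. No probe was saturated. An array's 75th percentile of signal was 520 to 598 on slides 1 and 2 and 782 to 819 on slide 3.

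Groups were compared with limma 3.58.1 in R 4.3.3, in one fit of all 9 arrays with Benjamini-Hochberg adjustment and a threshold of 0.05. The moderated spread had 2.55 prior degrees of freedom and 6 residual ones. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over 30 lists per comparison. Where a group had no array well above background, a fold is the bright group's mean over the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own. A p-value beside such a fold tests the fitted difference and not that bound. Named genes were fixed by rule before the data were examined: CD5, IL10 and TRPC1, the 12 largest called rises and falls per comparison with an official symbol and non-overlapping arrays, and up to 4 members with the smallest p per list described.

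On simulated data with the means and spreads of the 17763 genes, the E1A against control step recovered 80 of 100 genes planted at a log2 change of 1 and 96 of 100 at 2, with 3.30% of calls false. For E1B against control it recovered 87 and 97, with 8.00% false. For E1A against E1B it recovered 81 and 96, with 3.28% false. The simulated noise was independent between genes and arrays, without differences shared by many genes of an array. These shares therefore do not carry over to the real arrays. In the real comparison of E1A and control, 399 genes differed by at least 2-fold, and 4 of them were called.

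Replicate numbers coincide with slides. For E1A and control, the deviations of same-numbered arrays from their group means correlated at 0.27, 0.20 and 0.34, all over 0.1, so splits of these arrays were compared by the pairs they part, while the fit stayed unpaired. For E1B and control they correlated at 0.07, -0.47 and -0.19, and for E1A and E1B at 0.11, -0.04 and -0.04. Alternatives covered the background correction, normalization, probe filter, probe summary, slide block, arrays in the fit, variance moderation, outlier spots, the deposited table, the threshold and leaving out each array.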

Results

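Gene expression was measured in Jok-1 cells, a CD5-negative line from hairy cell leukaemia, on 9 one-colour oligonucleotide arrays. The control group held 3 arrays of untransfected cells. The E1A group held 3 arrays of cells given the cDNA of the membrane isoform of CD5, a B- and T-cell surface receptor. The E1B group held 3 arrays of cells given the cDNA of the cytoplasmic isoform. The labels name no empty-vector control, so a difference from control holds transfection as well as the isoform. They list G418, the selection drug, in the growth medium of every group. Whether the untransfected cells were grown in it is not known, so a difference may hold selection too. Each of 3 slides carried 1 array of every group, so replicate number and slide coincide. Of 41000 probes, 58.9% to 67.8% were well above background on an array, with the highest share on E1A replicate 1. The number of arrays limits the precision. After filtering, 17763 genes were tested with limma over all 9 arrays, and log2 values are relative to the 75th percentile of each array.

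CD5, the transfected gene, was first compared in every group. Its only probe lies on chromosome 11 at 60651410 to 60651457 of hg18, and whether the transfected cDNAs hold that stretch is not known. The probe was well above background on E1A replicate 1, at -4.69, and on none of the other 8 arrays. The mean was -6.78 ± 0.18 in control (SD, n = 3), -5.74 ± 0.93 in E1A and -6.51 ± 0.11 in E1B. All 3 E1A arrays lay above all 3 controls, 2 of them also below background, so no fold is given (exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow; limma adjusted p = 0.213 with this probe added to the tested ones). E1B against control had an exact permutation p of 0.2 and a limma adjusted p of 1.00, and E1A against E1B an exact permutation p of 0.2 and a limma adjusted p of 0.615. The order of arrays below background carries little weight, so CD5 does not settle the labels of single arrays.

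The first comparison set E1A cells against untransfected ones. VPREB1, which encodes part of the surrogate light chain of the precursor B-cell receptor, rose by 3.64 on the log2 scale in E1A cells (SE 0.23, limma adjusted p = 0.00184), from -5.73 ± 0.37 to -2.09 ± 0.09 (SD, n = 3 each). VPREB1 was well above background on 2 of 3 control arrays, and with the repaired normexp background, which adds an offset to dim signals, the difference was 1.49. SH2D1A, the signalling adaptor SAP of T and NK cells, was at least 3.91-fold higher in E1A (limma adjusted p = 0.0108). CEP112, a centrosomal protein gene, was at least 1.82-fold higher (limma adjusted p = 0.00293). FADS6, a member of the fatty acid desaturase family, was at least 1.58-fold higher (limma adjusted p = 0.0108). These bounds arise because SH2D1A, CEP112 and FADS6 were not well above background on any control array. Their p-values test the fitted log2 differences of 3.71, 3.09 and 2.97, not the bounds. With the repaired normexp background these differences were 0.72, 0.42 and 0.39, and none was called (limma adjusted p = 0.204, 0.317 and 0.394). EGLN1, the oxygen-sensing prolyl hydroxylase PHD2, fell by 0.95 (SE 0.11, limma adjusted p = 0.0441), and its 3 probes moved the same way. EGLN1 lost its call in 12 of 21 alternatives, against 1 of 20 for VPREB1. The planned normexp background, which failed as described below, was among the 12 and was the 1 for VPREB1. The probe of VPREB1 lies on chromosome 22 at 20929429 to 20929488 of hg18, and that of EGLN1 on chromosome 1 at 229568772 to 229568831. These 5 genes, 4 higher and 1 lower, were all that passed an adjusted p of 0.05, and in each the 3 arrays of E1A lay on one side of the 3 control arrays. At an unadjusted p under 0.05 there were 3139 genes, 1667 higher and 1472 lower.

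With slide as a block, only VPREB1 kept its call (adjusted p = 0.0434), so the count was 1. Within slides 1, 2 and 3, VPREB1 was higher in E1A by 4.09, 3.18 and 3.66, and EGLN1 was lower by -1.03, -0.84 and -0.97. The count depended on the E1B arrays, which share in the estimate of the spread: it was 572 with only the E1A and control arrays in the fit and 659 without E1B replicate 1. It was 2 without control replicate 1 or 3, 3 without control replicate 2 or E1A replicate 3, and 11 without E1A replicate 2.

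**Figure D1:**
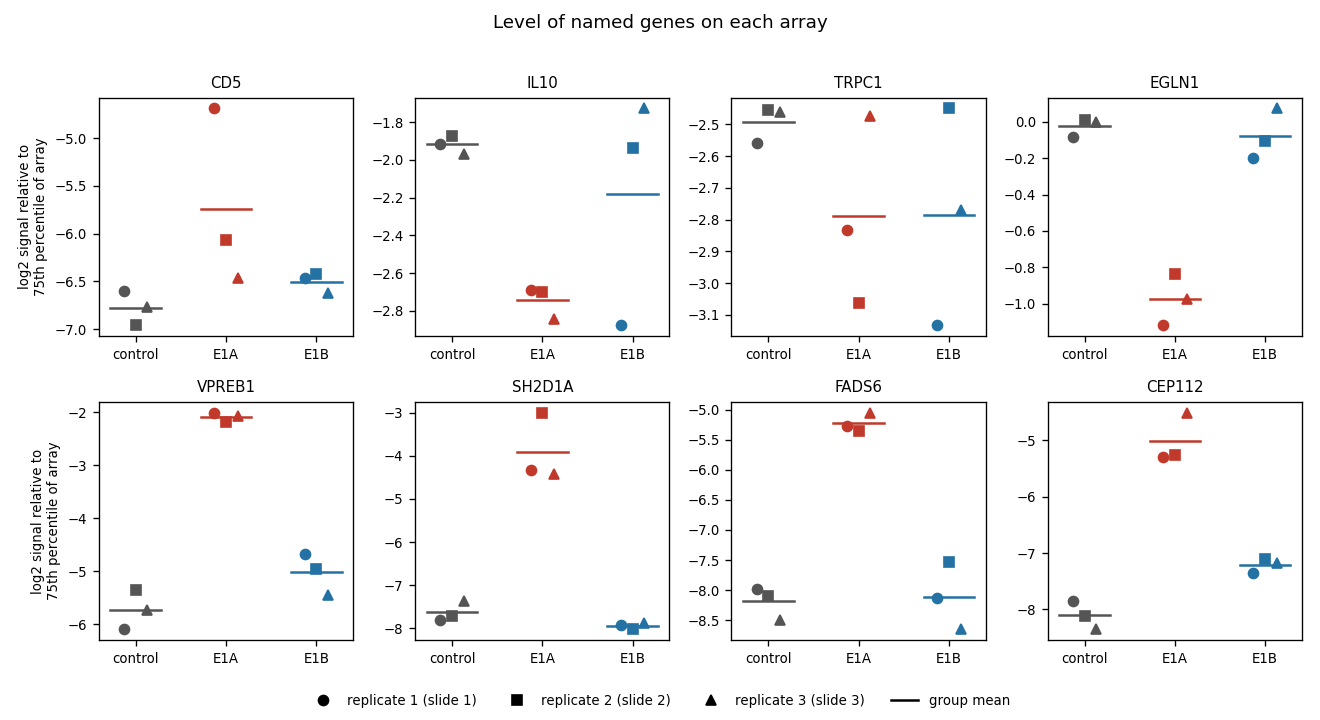
Log2 signal of 8 named genes relative to the 75th percentile of each array, with 1 point per array, symbols for replicate and slide, and a line at each group mean. VPREB1 lies between -2.18 and -2.01 on the E1A arrays and at -4.67 or lower on the others, while IL10 on E1B replicate 1, at -2.88, lies with the E1A arrays.

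Of 30 gene lists, 10 passed camera with a preset correlation between E1A and control, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.266. Targets of NF-kB, the inflammatory transcription factor, had a mean difference of -0.82 over 23 measured members. Of these, 19 fell when adjusted over the list alone and 0 did over all genes. CD40, the co-stimulatory receptor of B cells, was lower by -0.89 (SE 0.15). RGS1, a regulator of chemokine receptor signalling, was lower by -1.83 (SE 0.34). EBI3, a subunit of interleukins, was lower by -1.50 (SE 0.30), and IL4I1, an amino acid oxidase, by -0.90 (SE 0.18). Over all genes, CD40 and RGS1 were called in 3 of 21 alternatives and EBI3 and IL4I1 in 2. The list had a camera adjusted p of 1.25e-15 with a preset correlation, against an adjusted p of 0.266 with an estimated correlation. The estimated correlation came from the fit of all arrays, E1B included, and was 0.57 for this list in every comparison. The list mean was -0.74, 0.08 and -0.23 on E1B replicates 1, 2 and 3. It was -0.76, -0.84 and -0.86 on the E1A arrays and 0.08, -0.15 and 0.07 on the controls. The interferon response list below also varied within the other groups. No estimate is given without E1B replicate 1, so how far that array sets the estimated-correlation results is not known.

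Genes of cholesterol synthesis had a mean difference of -0.61, and 21 of 23 measured members fell when adjusted over the list alone, against 0 over all genes. MVK, mevalonate kinase, was lower by -1.01 (SE 0.21), and MVD, which makes isopentenyl diphosphate, by -0.96 (SE 0.20). INSIG1, a sterol sensor, was lower by -0.86 (SE 0.19), and EBP, a sterol isomerase, by -0.40 (SE 0.09). Over all genes, MVK, MVD, INSIG1 and EBP were each called in 2 of 21 alternatives. The camera adjusted p was 4.52e-14 with a preset correlation, against an adjusted p of 0.266 with an estimated correlation.

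Genes of antigen presentation through MHC class II had a mean difference of -0.44, and 13 of 15 fell when adjusted over the list alone, against 0 over all genes. HLA-DRA was lower by -0.55 (SE 0.08), HLA-DPB1 by -0.65 (SE 0.10), HLA-DQB1 by -0.73 (SE 0.12) and HLA-DPA1 by -0.65 (SE 0.12). Over all genes, HLA-DRA, HLA-DPB1 and HLA-DQB1 were each called in 3 of 21 alternatives and HLA-DPA1 in 2. The camera adjusted p was 5.52e-12 with a preset correlation, against an adjusted p of 0.266 with an estimated correlation. Of 19 measured MHC class I genes, 7 fell when adjusted over the list alone, with a list mean of -0.19. HLA-F was lower by -0.65 and HLA-B by -0.54. That list had a camera adjusted p of 0.00357 with a preset correlation, against an adjusted p of 0.266 with an estimated correlation. It missed the threshold with quantile normalization (adjusted p = 0.142).

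Cell-cycle genes had a mean difference of 0.27, and of 34 measured members 14 rose and 1 fell when adjusted over the list alone. MKI67, a proliferation antigen, was higher by 0.51 (SE 0.11), TTK, a mitotic kinase, by 0.44 (SE 0.10) and TOP2A, a topoisomerase, by 0.51 (SE 0.12). CCNE1, cyclin E1, fell by 0.50 (SE 0.12). The list had a camera adjusted p of 2.42e-06 with a preset correlation, against an adjusted p of 0.378 with an estimated correlation. By fry, a test of movement in one direction, the adjusted p was 0.0289 for NF-kB targets, 0.0374 for cholesterol synthesis, 0.00667 for MHC class II and 0.0561 for the cell cycle. For lists whose camera results follow or stand above, fry gave 0.0224 for MHC class I, 0.0584 for cytokines and 0.0115 for cytokine receptors. It gave 0.0387 for genes associated with chronic lymphocytic leukaemia, 0.00603 for hypoxia and glycolysis and 0.0374 for T-cell markers. With slide as a block, the camera adjusted p of the NF-kB targets was 5.98e-14 with a preset correlation, and no estimated correlation was run with the block; without it the adjusted p was 0.266.

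Cytokines and chemokines had a list mean of -0.69, and 3 of 19 fell when adjusted over the list alone. TNF was lower by -0.72 (SE 0.16), IL32 by -2.37 (SE 0.57) and CCL22, which was well above background on 2 of 3 E1A arrays, by -1.29 (SE 0.35), or -0.43 with the repaired normexp background. Of 17 cytokine receptor genes, 5 fell when adjusted over the list alone, among them IL7R, the interleukin-7 receptor, and IFNGR1, lower by -1.07 (SE 0.20). IL7R was well above background on 1 of 3 E1A arrays, so the size of its difference depends on the floor, at -2.25 here and -0.81 with the repaired normexp background. The camera adjusted p was 2.24e-04 for the cytokines and 0.00251 for the receptors with a preset correlation, against an adjusted p of 0.266 for both with an estimated correlation. IL10, an anti-inflammatory cytokine, was -2.74 ± 0.08 in E1A and -1.92 ± 0.05 in control (SD, n = 3), a difference of -0.83 (SE 0.25) that missed the threshold (limma adjusted p = 0.170). That SE includes the spread of the E1B arrays, whose SD for IL10 was 0.61. In 2 of 21 alternatives IL10 was called, at a limma adjusted p down to 0.00711. The exact two-sided permutation test of IL10 gave p = 0.1, the smallest that 3 against 3 arrays allow. TRPC1, a calcium-permeable channel, differed by -0.30 (SE 0.19, limma adjusted p = 0.470).

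Genes associated with chronic lymphocytic leukaemia had a list mean of -0.51, and 3 of 13 fell when adjusted over the list alone: RGS1, FCER2, the IgE receptor CD23, and CD200, an inhibitory ligand that was at least 3.33-fold lower in E1A. That list had a camera adjusted p of 0.0365 with a preset correlation, against an adjusted p of 0.266 with an estimated correlation. Even with the preset correlation it missed the threshold in 9 of 21 alternatives (camera adjusted p up to 0.247). The value of 0.247 came with the planned normexp background, which failed as described below. Others of the 9 were without E1A replicate 1 (0.0786), E1A replicate 3 (0.0729), control replicate 2 (0.202) or E1B replicate 3 (0.0581). Of 21 hypoxia and glycolysis genes, EGLN1, ALDOC (-1.23, SE 0.27) and PFKFB4 (-0.91, SE 0.25) fell when adjusted over the list alone, against EGLN1 alone over all genes. That list had a camera adjusted p of 0.0390 with a preset correlation, against an adjusted p of 0.266 with an estimated correlation. The hypoxia list missed the threshold in 6 of 21 alternatives (camera adjusted p up to 0.540). The value of 0.540 came with the planned normexp background, and quantile normalization gave 0.454. Others of the 6 were without E1A replicate 1 (0.0786), E1A replicate 2 (0.101) or control replicate 2 (0.0664).

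The interferon response list had a mean difference of 0.76, 0 of 31 members called, and a camera adjusted p of 0.00367 with a preset correlation, against an adjusted p of 0.658 with an estimated correlation. It missed the threshold without E1A replicate 1 (adjusted p = 0.0786) or E1A replicate 3 (adjusted p = 0.0872). By fry the list had an adjusted p of 0.403. Its level varied between arrays of 1 group, at 1.08, 0.17 and 1.02 on E1A replicates 1, 2 and 3 and at -0.25, 0.53 and -0.28 on the controls. Of 9 measured T-cell markers, SH2D1A and CD247, the T-cell receptor zeta chain, rose when adjusted over the list alone, the latter by 0.64 (SE 0.09), and the list had a camera adjusted p of 0.0955, against an adjusted p of 0.378 with an estimated correlation. With the preset correlation it passed in 6 of 21 alternatives, without control replicate 1 (adjusted p = 0.0374), E1A replicate 2 (0.0493) or E1A replicate 3 (0.0189), without a filter on dim probes (0.0162), with median scaling (0.0357) and with the deposited table (0.0350).

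The second comparison set E1B cells against untransfected ones. No gene passed an adjusted p of 0.05 by limma between E1B and control, 417 genes (2.35%) had an unadjusted p under 0.05, and the count was also 0 with slide as a block. VPREB1 differed by 0.71 (SE 0.23) without a call. IL10 differed by -0.26 (SE 0.25, limma adjusted p = 1.00) and TRPC1 by -0.29 (SE 0.19, limma adjusted p = 1.00). The NF-kB list mean was -0.74 on E1B replicate 1, 0.08 on replicate 2 and -0.23 on replicate 3. The cholesterol list mean was -0.61, -0.06 and 0.04 on those arrays, and the cell-cycle list mean was 0.30, -0.02 and 0.08. IL10 was -2.88 on E1B replicate 1, against -1.94 and -1.73 on the others. The NF-kB list passed camera with a preset correlation (adjusted p = 8.91e-07), against an adjusted p of 0.460 with an estimated correlation, and 0 of its 23 members were called. Without E1B replicate 1 the adjusted p of the NF-kB targets was 0.673, and over all alternatives it ranged from 1.41e-10 to 0.935. The value of 0.935 came with the planned normexp background, which failed as described below. Cholesterol synthesis (camera adjusted p = 9.44e-06), the cell cycle (2.57e-05), MHC class II (9.77e-04) and cytokines (0.0450) also passed with a preset correlation, against an adjusted p of 0.460 for each with an estimated correlation. Interferon genes had a camera adjusted p of 0.0162, against an adjusted p of 0.775 with an estimated correlation. Without E1B replicate 1 none of these lists passed, at an adjusted p of 0.897 for cholesterol synthesis and cytokines and 0.673 for the cell cycle, MHC class II and interferon, so these calls rest on that array. By fry with all arrays, the adjusted p was 0.499 for NF-kB targets and MHC class II and 0.532 for the cell cycle. It was 0.607 for cholesterol synthesis, 0.620 for cytokines and 0.970 for interferon. By camera, the cytokine list also missed the threshold with slide as a block (adjusted p = 0.0538) and without control replicate 1 (0.196) or 3 (0.120). The same held without a filter on dim probes (0.0697), with probes detected on all 9 arrays (0.053) and with the mean of a gene's probes (0.0546). The MHC class II list missed the threshold without control replicate 2 (0.0651) and with quantile normalization (0.0627). The interferon list missed it without control replicate 1 (0.191) or 3 (0.197) or E1B replicate 3 (0.452).

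**Figure D2:**
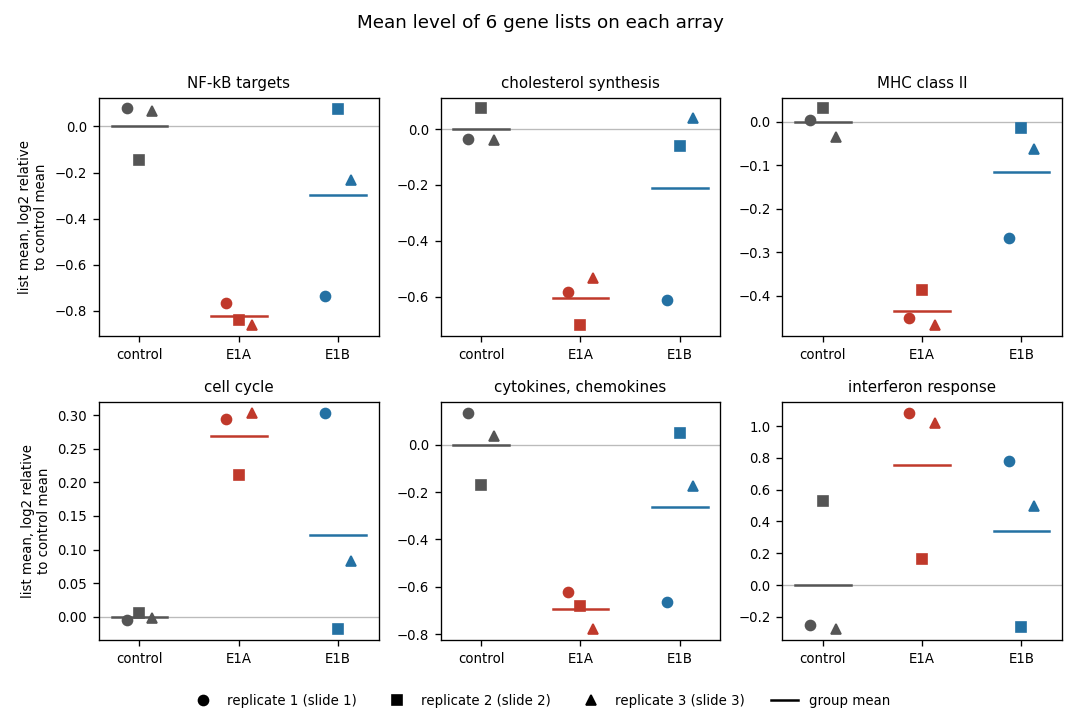
Mean log2 level of 6 gene lists on each array relative to the control mean, with 1 point per array, symbols for replicate and slide, and a line at each group mean. On the NF-kB list E1B replicate 1, at -0.74, lies beside the E1A arrays, and E1B replicate 2, at 0.08, beside the controls.

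The third comparison set the isoforms against each other. VPREB1 was higher in E1A than in E1B by 2.94 (SE 0.23, limma adjusted p = 0.0110). SH2D1A was at least 4.32-fold higher (limma adjusted p = 0.0110), CEP112 at least 2.01-fold (limma adjusted p = 0.0230) and FADS6 at least 1.75-fold (limma adjusted p = 0.0146). SH2D1A, CEP112 and FADS6 were not well above background on any E1B array. These 4 genes were all that passed, and 0 passed with slide as a block, where the adjusted p of VPREB1 was 0.0929. At an unadjusted p under 0.05 there were 1558 genes. With the repaired normexp background none of the 4 genes passed. VPREB1 was then at 1.36 (limma adjusted p = 0.0786), SH2D1A at 0.76, CEP112 at 0.27 and FADS6 at 0.31. Of 15 MHC class II genes, 8 fell in E1A when adjusted over the list alone, HLA-DRA by 0.41 (SE 0.08), and the list had a camera adjusted p of 2.06e-12 with a preset correlation, against an adjusted p of 0.268 with an estimated correlation. Of 23 NF-kB targets, 9 fell when adjusted over the list alone, and the list had a camera adjusted p of 5.73e-13 with a preset correlation, against an adjusted p of 0.365 with an estimated correlation. Cholesterol synthesis had a camera adjusted p of 1.66e-11 with 0 members called, against an adjusted p of 0.444 with an estimated correlation. By fry the adjusted p was 0.0356 for MHC class II, 0.186 for NF-kB targets and 0.247 for cholesterol synthesis. On slide 1, which holds E1B replicate 1, the E1A and E1B arrays differed less than on the others: the NF-kB mean difference was -0.03, -0.92 and -0.63 on slides 1, 2 and 3, that of cholesterol synthesis 0.03, -0.64 and -0.57, and that of MHC class II -0.18, -0.37 and -0.41. The count of changed genes was 256 without E1B replicate 1, 9 without E1A replicate 2, 2 without E1A replicate 1 or E1B replicate 3 and 1 without E1B replicate 2.

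With 0 genes called by limma in E1B against control (417 at an unadjusted p under 0.05), the overlap of called genes is 0 whatever the cells share, and it says nothing about shared effects. Across genes, the log2 differences of E1A and E1B from control had a Pearson r of 0.64 and a covariance of 0.0449. Unchanged groups set against the same controls gave a mean r of 0.50 and a covariance of 0.0202 in 100 simulations. The covariance exceeded that by 0.0247. The 3 controls could not be split into 2 sets of at least 2 arrays, so part of the excess may come from the shared controls. Without E1B replicate 1, r was 0.32, below the mean of 0.50 that unchanged groups gave with all arrays. No unchanged value and no covariance are given without that array, so 0.32 cannot be read as a shared response. The excess of 0.0247 is shown only with E1B replicate 1 included, and whether any remains without it is not known. Genes are not independent replicates, so no p is given.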

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

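The tests of wrong labels, of slide and of T cells were chosen only after the values they measure had been seen in part. The tests of splits, of precursor B cells and of single interferon genes were written before.

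4 genes differed between the transfectants in the direct test of E1A against E1B: VPREB1 by 2.94, SH2D1A by 4.03, FADS6 by 2.89 and CEP112 by 2.20 on the log2 scale, of which the last 3 are fitted values against a group below background.

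The 3 E1B arrays did not lie together, and an E1A array under the label of E1B replicate 1 could account for part of this: on genes over 2-fold apart between 2 E1A arrays and the controls and well above background on all 9 arrays, it lay nearer the E1A mean on at most 87.3%, against 70.2% to 98.2% for held-out E1A arrays and 2.99% or less for E1B replicates 2 and 3. Other genes speak against a wrong label. Of 47 genes measured on all E1A and no control arrays, a set tried earlier, 46.8% lay nearer E1A on E1B replicate 1. That share was 66.7% to 97.9% for held-out E1A arrays and 27.7% and 23.4% for E1B replicates 2 and 3. EGLN1 was -0.20 on E1B replicate 1 against -1.12 to -0.83 on E1A arrays, and VPREB1 -4.67 against -2.18 to -2.01. On the same slide, E1A replicate 1 exceeded E1B replicate 1 by 3.61 in SH2D1A, 2.87 in FADS6 and 2.07 in CEP112. Each is a difference between single arrays against a signal not well above background, so its size depends on the floor. These 5 genes were called in a fit in which an E1B array lying apart counts against a call, and the rule for this test was revised 3 times after values were seen, its first version excluding a wrong label, so the question stays open. Slide is argued against, since control and E1A replicates 1 shifted in the NF-kB list by -15.6% of the shift of E1B replicate 1, the opposite way. Whether E1B replicates 2 and 3 are control arrays could not be decided. Against the controls, 1.98% of genes had an unadjusted limma p under 0.05. Over centred genes, E1B replicate 2 correlated with control replicates 1, 2 and 3 at 0.57, -0.13 and 0.63. For E1B replicate 3 these correlations were -0.22, 0.42 and -0.15. The 2 E1B arrays correlated with each other at -0.23, so taking them together hides that they differ. The rule asked for over 0.2 with each control, which the controls themselves did not reach, at -0.20 to 0.57. It therefore could not decide. By the SD of log2 differences, E1B replicate 2 lay closest to control replicate 3 (0.185) and E1B replicate 3 to control replicate 2 (0.272). Between controls that SD was 0.199 to 0.358. An effect of the isoform that varies between cultures was not tested.

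SH2D1A, CEP112 and FADS6 were measured on E1A arrays and on no control array. T cells as the whole source are argued against, since 0 of the 5 abundant T-cell transcripts not measured on all controls were measured on all E1A arrays, CD3D and ZAP70 on none, and a count of all 12, tried first, was 7 in both groups and could not separate them. 2 of the 12 did lie above every control on all E1A arrays, CD28 (mean -4.91 against -7.98, well above background on 1 E1A array) and LCK (-0.15 against -0.99), and what sets them apart stays open. Precursor B cells are argued against too: 1 of 12 transcripts, CD79B, was measured on all E1A arrays and higher there than on every control, LEF1 lay higher there without being well above background, and DNTT, RAG1 and RAG2 were not measured on any array. Clonal differences between the cultures were not tested.

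Interferon genes differed between arrays of 1 group. Slide accounted for 16.0% of the variance of the list mean left after group. On control replicate 2 the rise was spread over the list, since 24 of 31 members were higher there than on both other controls. That count of members does not show how far a few large ones set the list mean. The E1A and E1B arrays were not tested in this way. No biological explanation was tested.

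The 10 splits of 3 against 3 arrays are too few for a share under 0.05. The real split of E1A and control called 5 genes and the highest other 1, and it was the only 1 with as many. The 3 other splits that part all 3 pairs called 0. For E1A against E1B these were 4 and 3 genes, with 1 split giving as many. For E1B against control the real split called 0 and the split of control 2, E1B 1 and E1B 3 against the rest 289, and all 10 gave at least 0. That count points to a structure among the arrays that the labels do not describe. The split differs from the labels by an exchange of control 2 and E1B 2, both on slide 2. The interferon list mean was 0.53, 0.78 and 0.50 on control 2, E1B 1 and E1B 3. On control 1, control 3 and E1B 2 it was -0.25, -0.28 and -0.26. By the SD of log2 differences, E1B 1 lay 0.377 from control 2 and 0.380 from E1B 3. An exchange of labels was not tested, and the 0 calls rest on the labels as given. Lists past the set test numbered 10 against a highest other of 7 for E1A and control (1 split as many), 6 against 6 for E1B and control (4 splits) and 7 against 9 for E1A and E1B (4 splits).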

How the results depend on the processing

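Alternatives marked as added were chosen after the data were seen: the threshold of 0.1, leaving out arrays of the group not compared, and a repaired normexp. CD5 was not called in any alternative, and its difference turned negative only with the planned normexp (fitted values of -0.94 for E1A and -0.93 for E1B against control and -0.00767 for E1A against E1B). E1B against control called 0 genes in every alternative, which fixes the overlap of the transfectants at 0.

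For E1A against control, the 5 genes became 1 with quantile normalization, 1 without a filter on dim probes, 0 with probes detected on all 9 arrays (where of the 5 only EGLN1 is still tested), 22 with the median (6 higher, 16 lower, with the median gene at -0.09), 38 with the deposited table (7 higher, 31 lower), 46 with trend and robust moderation, 572 with the 2 groups alone and 67 at the added threshold of 0.1. The counts 22, 38, 46 and 572 each held all 5 genes. For E1A against E1B, the 4 genes became 1 with quantile normalization, 0 without the filter, 0 with probes detected on all 9 arrays and 1 with the 2 groups alone. With the replicate block, which is the slide, the counts were 1, 0 and 0. Leaving out 1 array gave 2 to 659 genes for E1A against control and 1 to 256 for E1A against E1B, each highest count without E1B replicate 1. The correlation of 0.64 was 0.45 without the filter and ranged from 0.32 to 0.72 with 1 array left out. The cause was not tested beyond the changes in arrays and genes named.

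The planned normexp correction failed on control replicate 3. Local backgrounds of up to 79950, flagged by the scanner software, raised its fitted noise SD to 1351, against 0.618 to 8.07 on the other arrays. Its values are therefore not evidence about the cells: 0 genes for E1A against control, 0 for E1A against E1B, a correlation of 0.93, and reversed signs for CEP112 (-0.69), FADS6 (-0.72) and SH2D1A (-0.36) in E1A against control and, in E1B against control, for the lists of interferon response (-0.15), MHC class II (0.0866), B-cell receptor signalling (0.0906) and apoptosis (0.0430). With flagged backgrounds replaced, as added, the noise SD was 0.393, no called result reversed, and the counts were 7 for E1A against control (2 of the 5 genes), 0 for E1B against control and 0 for E1A against E1B, with a correlation of 0.67. That setting adds an offset of 50 to each signal, which lowers the fold of dim probes, and its fitted values for E1A against control lay nearer 0 than those of the report: VPREB1 1.49 (limma adjusted p = 0.0330), SH2D1A 0.72, CEP112 0.42, FADS6 0.39, BACH2 0.15 and FOS 0.45, with CD200 -0.61, IL7R -0.81, FCER2 -0.99 and CCL22 -0.43, while EGLN1 (-0.83) and IL32 (-2.03) moved less. The bounds given for SH2D1A, CEP112, FADS6, CD200 and BACH2 therefore hold only for the processed signal without that offset.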

Other observations

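The following genes were chosen after their values were seen. The B-cell identity list had 16 members higher and 12 lower in E1A than in control and a camera adjusted p of 0.987. In it, BACH2, a repressor of plasma cell differentiation, was at least 1.35-fold higher (limma adjusted p = 0.117), FCER2, the low-affinity IgE receptor CD23, was lower by -1.78 (SE 0.34, limma adjusted p = 0.110) and MS4A1, which encodes CD20, by -0.49 (SE 0.10, limma adjusted p = 0.110). CD200, an inhibitory ligand, was at least 3.33-fold lower (limma adjusted p = 0.0905). Among genes induced by ERK signalling, EGR2 was lower by -0.80 (SE 0.16) and DUSP2 by -0.55 (SE 0.13). Over the alternatives EGR2 ranged from -1.15 to -0.39. FOS was higher by 1.37 (SE 0.34), or 0.45 with the repaired normexp background. MYC was higher by 0.41 (SE 0.10), with 1 of its 3 probes the other way. The 2 directions left that list with a camera adjusted p of 0.511. DNMT3B, a DNA methyltransferase, was higher by 0.56 (SE 0.11, limma adjusted p = 0.110). None of these passed the threshold over all genes with the main settings. In the alternatives, CD200 passed in 5 of 20 and FCER2 in 3 of 21, while BACH2 and MYC passed in none.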
